A study of Mus musculus with 8 samples.

How the data were processed

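Small RNA was sequenced from CD8+ T cells sorted from mouse spleen, in 8 libraries that fall into 4 groups of 2. The groups combine a genotype, WT or mCre, with a sorted subset, TN or MP, as the sample titles give them. Per the labels' protocols, cells were enriched on magnetic beads, sorted on CD8, CD4, CD44 and CD122, lysed in Trizol, and made into libraries with a ligation-based small RNA kit and size selection for miRNA-length inserts. The protocol text covers adult and neonatal spleens together, and the age of each sample is not given in the sources used here. The labels do not say that the libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical.

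The authors deposited one table of expected counts with 2128 rows, each a mature miRNA on one precursor, and 1978 distinct mature names. Of these names, 85 stood in more than 1 row. Among names in 1 row, 82.8% of the values above 0 were whole numbers, to within 0.011, against 15.8% among names in several rows. The values thus look like read counts in which a read that matches several rows was divided between them; this was read from the values. Per the submitters' processing notes the genome build was mm10; the aligner, the counting tool and the miRNA annotation are not given in the sources used here. All 8 sample columns were matched to titles by replicate number, genotype and subset. Near-identical family members can share reads in such counting, so values of single members of let-7, miR-29b, miR-181, miR-486 and the Sfmbt2 cluster are uncertain to that extent.

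The rows of each mature miRNA were summed and rounded to whole counts. Totals ran from 1936600 to 5230975 counts per library, a 2.7-fold range, and 880 mature names had a count above 0 in at least 1 library. Shares of counts for single libraries carry 95% Wilson intervals, and a count of 0 was read as allowing up to 3 counts. Intervals and floors cover counting error only, since the reads carry no molecular identifiers that were used here. Low counts were filtered with filterByExpr of edgeR 4.0.16 over the 4 groups, with a minimum count of 10 and a minimum total count of 15, which left 382 miRNAs. TMM factors scaled the libraries. CPM values follow TMM scaling unless said otherwise; shares in percent are of all miRNA counts, unscaled. Log2 CPM for the principal components used a prior count of 2.

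The main test was the quasi-likelihood F test of edgeR in R 4.3.3 with robust estimation and Benjamini-Hochberg adjustment over the 382 miRNAs, at an adjusted p under 0.05. One fit of the 4 groups, with 4 residual degrees of freedom, gave mCre against WT in each subset, MP against TN in each genotype, and the difference of the genotype effect between subsets. An additive fit of subset and genotype, with 5 residual degrees of freedom, gave mCre against WT over both subsets and MP against TN over both genotypes. The 4-group fit had a common dispersion of 0.356. Standard errors (SE) of log2 fold changes were the absolute fold change divided by the square root of F. Lists of miRNAs were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists with at least 3 tested members; camera with an estimated correlation and fry were the alternatives.

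The comparisons, tests, alternatives and 19 lists were fixed before the data were examined. The lists were the miR-29, let-7, miR-17-92, miR-181, miR-15/16, miR-30 and joint miR-130 and miR-301 families, the miR-183 (with miR-96 and miR-182), miR-23/27/24 and miR-99/100/125 clusters, miRNAs of T cell activation and of resting lymphocytes, the Dlk1-Dio3 and Sfmbt2 clusters, and markers of myeloid, erythroid, endothelial and stromal, epithelial, and liver, muscle and neural cells. Members of the Sfmbt2 list were taken by the start of their names, not by genomic position. The miRNAs named in the text follow a rule fixed at the same time. In each comparison it takes every tested miR-29 form, and, among miRNAs past the threshold without overlap between the compared libraries, the 8 with the largest change per direction. It adds the 4 most abundant miRNAs past the threshold per direction and up to 4 members per list by smallest p. Where fewer than 5 miRNAs passed, the 5 with the smallest p are named as not past the threshold. The 5 most abundant miRNAs over all libraries are named as well. Not every miRNA that the rule takes is printed in the text.

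On counts simulated from the real means, library sizes and dispersions, with 200 changed miRNAs in each of 5 draws and 385 tested on average, mCre against WT in TN recovered 0% of 2-fold and 2.3% of 4-fold changes. For MP against TN over both genotypes, with 387 tested on average, recovery was 0.5% of 2-fold and 32.9% of 4-fold changes. Unchanged miRNAs were called at 0.07% and 0.2%. The draws were independent between miRNAs, so these rates do not cover a shift that many miRNAs of a library share.

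Alternatives were RLE factors, total count scaling, TMM without the miR-29 family, no filter beyond a count above 0, DESeq2 1.42.0, the replicate number as a block, a fit of the compared groups alone, and leaving out each library in turn. For the miR-29 share they were the 3p forms alone and leaving out the most abundant miRNA. Added after seeing the data were a fit without both TN replicate 2 libraries, the mean of rows in place of their sum, and the removal of a loess trend (span 0.75) on the GC content of the hairpin arm per library. Hairpin positions, host genes and arm sequences came from GENCODE M21 on GRCm38, which matches mm10; 379 of the 382 tested miRNAs (99.2%) had an arm GC value. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, intervals and plots.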

Results

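The series profiled miRNAs of splenic CD8+ T cells from WT mice and from mice labelled mCre, sorted into the subsets TN and MP. Its design text uses VM where the titles use MP. In this field TN usually stands for true naive cells and VM for virtual memory cells, which carry memory markers such as CD44 and CD122 without having met antigen; the labels do not spell these terms out. The series title ties the samples to miR-29 and Cre, a recombinase used to delete marked genes, without naming the deleted sequence. Each of the 4 groups held 2 libraries. The WT TN libraries held 3024888 and 1936600 counts, the WT MP libraries 3295386 and 3920356, the mCre TN libraries 5230975 and 2921829, and the mCre MP libraries 2140363 and 3061370.

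The let-7 family, which is abundant in resting lymphocytes, led every library. let-7f-5p averaged 22.2% of the counts over the 8 libraries (range 17.3% to 28.7%), let-7g-5p 11.4%, let-7a-5p 9.66%, miR-92a-3p of the miR-17-92 cluster 8.34%, and miR-150-5p, a miRNA of mature lymphocytes, 8.09% (range 3.84% to 15.2%). No pair of replicates agreed within counting noise (chi-square per degree of freedom from 281 to 1663), so none was treated as 1 library given in duplicate.

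The miR-29 family was read first, as the miRNA named in the series title. miR-29a-3p made up nearly all of it. In WT cells the family took 0.216% ± 0.196 of the counts in TN and 0.753% ± 0.544 in MP (SD, n = 2 each). In mCre cells it took 0.880% ± 1.00 in TN and 0.106% ± 0.0386 in MP (SD, n = 2 each). Among MP libraries both mCre values, 0.0787% and 0.133%, lay below both WT values, 0.369% and 1.14%. Among TN libraries, replicate 1 had 0.355% in WT and 0.170% in mCre, with Wilson intervals of 0.348% to 0.362% and 0.166% to 0.174%. Replicate 2 ran against the labels: the library labelled WT held 0.0775% (0.0736% to 0.0815%) and the library labelled mCre 1.59% (1.58% to 1.61%), the highest of the 8. Every genotype direction that follows for TN, or over both subsets, draws on these 2 libraries as labelled.

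**Figure D1:**
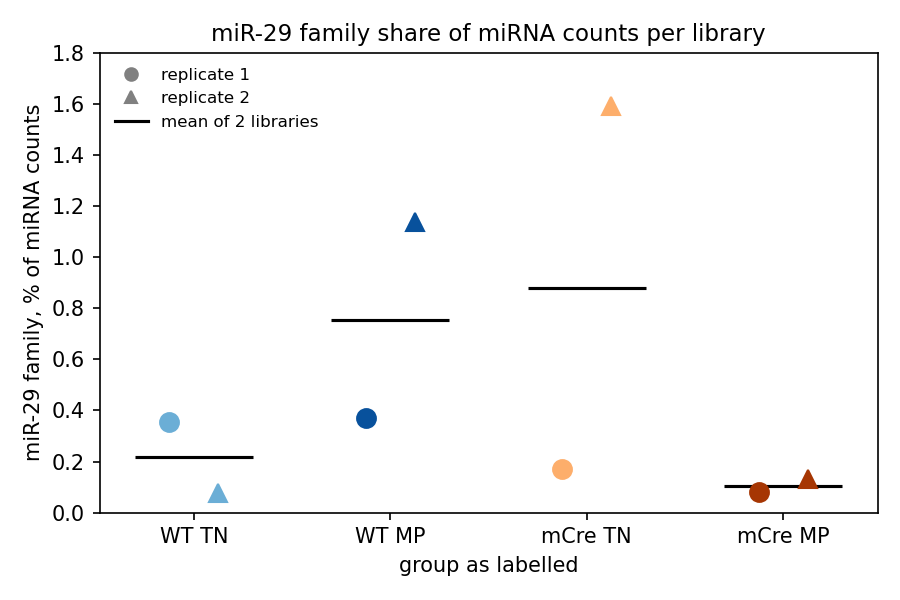
Share of miRNA counts taken by the miR-29 family (vertical axis, percent) in each library, by group as labelled (horizontal axis); circles are replicate 1, triangles replicate 2, and lines the mean of 2 libraries. The TN replicate 2 library labelled WT sits at 0.0775% and that labelled mCre at 1.59%.

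The miR-29 forms come from a pair of clusters (GRCm38, mm10). Mir29a lies on chromosome 6 at 31062660 to 31062747 and Mir29b-1 at 31063023 to 31063093, both on the minus strand and inside no other annotated gene. Mir29b-2 lies on chromosome 1 at 195037040 to 195037120 and Mir29c at 195037547 to 195037634, both on the plus strand in exons of the noncoding gene A330023F24Rik and opposite exons of Cd46. Mature miR-29b-3p can come from either cluster, while miR-29a-3p comes from the chromosome 6 cluster and miR-29c-3p from the chromosome 1 cluster. In MP, miR-29a-3p was 1165 ± 470.5 CPM in mCre against 7382 ± 6048 in WT, miR-29b-3p 54.8 ± 22.8 against 291.3 ± 210.6, and miR-29c-3p 5.64 ± 0.263 against 31.9 ± 16.5 (SD, n = 2 each). All 3 were thus lower in both mCre MP libraries than in both WT MP libraries, an absence of overlap that chance gives in 33.3% of comparisons of 2 libraries with 2. In this comparison 247 of the 382 miRNAs tested (64.7%) lacked overlap, so the separation does not single out miR-29.

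MP cells were compared with TN cells over both genotypes, which asks what sets the subsets apart. miR-146a-5p, a feedback inhibitor of NF-kB signalling in lymphocytes, rose 6.09-fold, from 2406 ± 865 CPM in TN to 14410 ± 2219 in MP (SD, n = 4 each). miR-21a-5p, which is induced on T cell activation, rose 3.65-fold, from 16690 ± 4988 to 60150 ± 14000 CPM. miR-181a-5p, which sets the sensitivity of the T cell receptor in developing T cells, fell 7.88-fold, from 6636 ± 4785 to 790.8 ± 340.9 CPM, and the partner strands of both its hairpins fell with it. All 4 MP libraries lay on one side of all 4 TN libraries for each of the 9 miRNAs past the threshold, and for 43 of the 382 tested (11.3%, against 2.9% by chance).

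Of 382 miRNAs, 9 passed the adjusted threshold in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5 higher and 4 lower in MP. miR-146a-5p changed by 2.61 ± 0.37 on the log2 scale (SE, edgeR adjusted p = 0.0137) and miR-181a-2-3p by -3.40 ± 0.43 (edgeR adjusted p = 0.01102). The others higher in MP were miR-30a-3p (2.13 ± 0.37), miR-30c-2-3p (2.44 ± 0.48), miR-21a-5p (1.87 ± 0.36) and miR-598-3p (5.54 ± 0.94), with edgeR adjusted p from 0.0303 to 0.0392. miR-598-3p was scarce in TN, at 0.211 ± 0.252 CPM against 12.9 ± 4.60 in MP, so its fold is poorly fixed. The others lower in MP were miR-181a-5p (-2.98 ± 0.61), miR-211-5p (-2.35 ± 0.43) and miR-181a-1-3p (-2.29 ± 0.46), with edgeR adjusted p from 0.0332 to 0.0424. DESeq2 called 28 miRNAs, 10 higher and 18 lower, among them all 9, and edgeR without the filter on low counts 19, also with all 9. The split of 5 higher and 4 lower became 4 and 6 with RLE factors and 4 and 5 with total count scaling. The number of calls was 0 without WT MP replicate 1, WT MP replicate 2 or mCre MP replicate 2, 1 without WT TN replicate 1 or mCre TN replicate 1, 2 without the library labelled mCre TN replicate 2 or mCre MP replicate 1, and 41 without the library labelled WT TN replicate 2. Without both TN replicate 2 libraries, a choice made after seeing the data, it was 49, the 9 included.

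**Figure D2:**
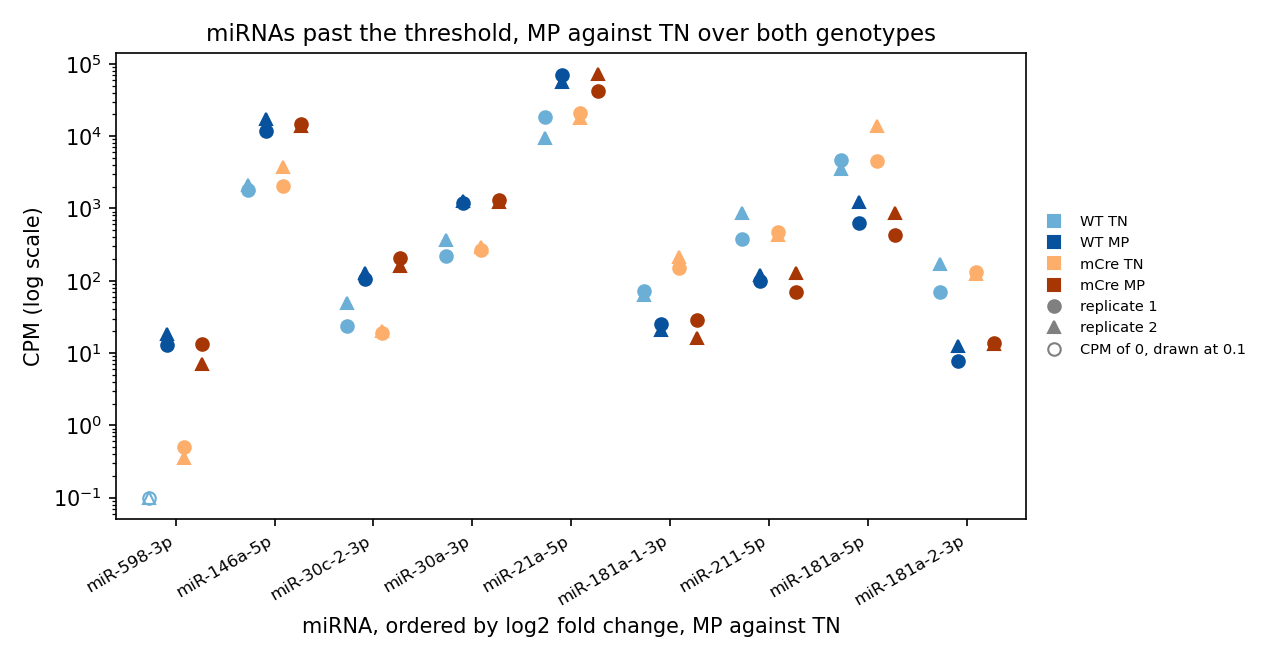
CPM per library (vertical axis, log scale) of the 9 miRNAs past the threshold for MP against TN over both genotypes, ordered by fold change; colours are groups, circles replicate 1, triangles replicate 2, and open symbols a CPM of 0. miR-146a-5p averaged 14410 CPM in MP and 2406 in TN, and miR-181a-5p 790.8 and 6636.

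Mir146, which gives miR-146a, lies on chromosome 11 at 43374397 to 43374461, inside no other annotated gene. Mir21a lies on the same chromosome at 86584067 to 86584158, in an exon of Vmp1. Mir181a-1 lies on chromosome 1 at 137966455 to 137966541 in an intron of Gm4258, and Mir181a-2 on chromosome 2 at 38852735 to 38852810, opposite an intron of Nr6a1. Mir30a and Mir30c-2 are neighbours on chromosome 1, at 23272269 to 23272339 and 23291701 to 23291784. Mir211 lies on chromosome 7 at 64205806 to 64205911 in an intron of Trpm1, and Mir598 on chromosome 14 at 63727189 to 63727267 in an intron of Xkr6.

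Several miRNA groups moved between the subsets as a whole by camera with its preset correlation, and none of these calls held with an estimated correlation. By fry, the other alternative, the miR-183 (fry adjusted p = 0.005083), T cell activation (0.03328) and miR-99/100/125 (0.01609) lists held. The miR-181 and Sfmbt2 lists did not (fry adjusted p = 0.1687 for both). All 3 members of the miR-183 cluster, which is induced by cytokine signals in T cells, were higher in all 4 MP libraries (camera adjusted p = 0.0009197; 0.2889 as adjusted p with an estimated correlation). miR-182-5p changed by 1.73 ± 0.39 and miR-183-5p by 1.83 ± 0.47 on the log2 scale; 0 of 3 members passed over all miRNAs tested and 3 of 3 adjusted over the list alone. The T cell activation list had 7 of 8 tested members higher (camera adjusted p = 0.005522; 0.3734 as adjusted p with an estimated correlation), and miR-146a-5p and miR-21a-5p passed both over all miRNAs and adjusted over the list alone. miR-155-5p, needed for effector responses of CD8+ T cells, changed by 1.27 ± 0.55 with overlap between the subsets, and miR-132-3p, the member that went the other way, by -1.12. All 4 miR-181 members were lower (camera adjusted p = 0.005522; 0.4653 as adjusted p with an estimated correlation); miR-181a-5p passed over all miRNAs, and miR-181b-5p (-2.54 ± 0.61) joined it adjusted over the list alone. All 5 members of the miR-99/100/125 clusters were lower (camera adjusted p = 0.02188; 0.3022 as adjusted p with an estimated correlation), and miR-99b-5p (-1.54 ± 0.36) and miR-125a-5p (-1.37 ± 0.38) passed adjusted over the list alone. The Sfmbt2 cluster, a rodent repeat of miRNA copies, had 36 of 38 tested members lower in MP (camera adjusted p = 3.172e-05; 0.4653 as adjusted p with an estimated correlation) and 0 past the threshold over all miRNAs or adjusted over the list alone; its copies share reads, and its median moved from -1.002 to -0.56 with the GC trend removed. The directions of these 5 list medians held under RLE, total count and miR-29-free TMM scaling.

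The remaining lists did not pass for MP against TN over both genotypes. Camera adjusted p was 0.5274 for miR-29, 0.9645 for let-7, 0.3223 for miR-17-92 (11 of 13 members lower), 0.7881 for miR-23/27/24, 0.7881 for resting lymphocyte miRNAs, 0.5274 for miR-15/16 and 0.7881 for miR-30. Within the resting lymphocyte list, miR-139-5p was 6216 ± 1084 CPM in MP and 1918 ± 1427 in TN (SD, n = 4 each), a log2 change of 1.92 ± 0.58 that did not pass (edgeR adjusted p = 0.1945). Among miRNAs typical of other cell types, the lists gave camera adjusted p of 0.5895 for erythroid, 0.5274 for epithelial and 0.4601 for liver, muscle and neural markers. The myeloid and the endothelial and stromal lists had 2 tested members each, the miR-130 and miR-301 family 1 and the Dlk1-Dio3 cluster 0, which was too few for camera. Myeloid miRNAs held 1.40 to 13.7 CPM and erythroid miRNAs 81.6 to 272.9 CPM in the 8 libraries, without TMM scaling. Epithelial list members held 2641 to 5994 CPM, among them miR-200b-3p with 1339 ± 338.4 CPM in MP and 740.2 ± 476.6 in TN (SD, n = 4 each). Endothelial and stromal miRNAs held 22.2 to 112.3 CPM, liver, muscle and neural miRNAs 14.0 to 38.8 CPM, and the Dlk1-Dio3 cluster 0.765 to 10.3 CPM.

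MP was compared with TN within WT to see the subset difference without the mCre genotype. miR-146a-5p was 14450 ± 3804 CPM in WT MP and 1960 ± 236.2 in WT TN, miR-21a-5p 63130 ± 10340 and 13840 ± 6093, and miR-155-5p 2306 ± 400.0 and 460.2 ± 89.9 (SD, n = 2 each). miR-181a-2-3p was 10.2 ± 3.33 CPM in MP and 120.6 ± 71.7 in TN. miR-598-3p had 0 counts in both TN libraries and 115 in MP, 26.4-fold higher with the floor of 3 counts taken over the group. The exact 95% interval of the MP to TN ratio started at 21.1, from counting alone. These 5 miRNAs had the smallest p, and none passed. edgeR's quasi-likelihood test called 0 of 382 (smallest edgeR adjusted p = 0.0618), with 31 at an unadjusted p under 0.05, while DESeq2 called 12. Without WT TN replicate 1 edgeR called 6, without the filter on low counts 6, and without both TN replicate 2 libraries 14. The activation list was higher (camera adjusted p = 0.0005031, and 0.2503 as adjusted p with an estimated correlation), with 5 of 8 members past the threshold adjusted over the list alone and 0 over all miRNAs. It also passed by fry (fry adjusted p = 0.006324), while the miR-29 and Sfmbt2 lists did not (0.2474 and 0.5988). The miR-29 list was higher in MP, in 6 of 6 forms (camera adjusted p = 0.02962; 0.4548 as adjusted p with an estimated correlation), and its TN side includes the low replicate 2 library labelled WT; without both TN replicate 2 libraries its median moved from 2.04 to 1.27 on the log2 scale. The Sfmbt2 cluster was lower in 36 of 38 members (camera adjusted p = 0.001897; 0.6113 as adjusted p with an estimated correlation), with a median of -0.87, and -1.34 without both TN replicate 2 libraries.

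The subset difference was then taken within mCre. miR-181a-5p was 649.8 ± 303.2 CPM in MP and 9174 ± 6500 in TN, miR-183-5p 522.1 ± 113.5 and 84.98 ± 3.86, miR-30c-2-3p 180.4 ± 32.5 and 19.5 ± 0.824, and miR-146a-5p 14370 ± 535.8 and 2852 ± 1180 (SD, n = 2 each). miR-181a-1-3p and miR-181a-2-3p completed the 5 smallest p with miR-181a-5p, miR-183-5p and miR-30c-2-3p, at log2 changes of -3.03 ± 0.55 and -3.23 ± 0.62. Of the miR-29 forms, miR-29a-3p changed by -2.85 ± 1.191, miR-29b-3p by -2.708 ± 1.169 and miR-29c-3p by -2.162 ± 1.468 (SE). miR-29a-5p had 0 counts in MP and 31 in TN, miR-29c-5p rose by 4.119 ± 1.462, and miR-29b-1-5p changed by 0.22 ± 1.083. Without both TN replicate 2 libraries the miR-29 list median moved from -2.435 to -0.162. edgeR's quasi-likelihood test called 0 of 382 (smallest edgeR adjusted p = 0.08288), with 82 at an unadjusted p under 0.05, and DESeq2 called 44. By camera the miR-181 family was lower and the miR-183 cluster higher (both adjusted p = 0.005863, and 0.7554 and 0.4041 as adjusted p with an estimated correlation), with 3 of 4 and 2 of 3 members past the threshold adjusted over the list alone. By fry the miR-183 cluster also passed (fry adjusted p = 0.001484), while the miR-181, Sfmbt2 and miR-17-92 lists did not (0.2056, 0.2431 and 0.3254). The Sfmbt2 cluster was lower in 32 of 38 members (camera adjusted p = 0.005863; 0.7554 as adjusted p with an estimated correlation), and the miR-17-92 list in 13 of 13 (camera adjusted p = 0.02467; 0.7554 as adjusted p with an estimated correlation), with 0 members adjusted over the list alone in either. The TN side holds the library labelled mCre TN replicate 2, with 1.84% miR-181 against 0.707% in replicate 1; without both TN replicate 2 libraries the miR-181 list median moved from -3.60 to -1.82 on the log2 scale. Both mCre MP libraries stood apart from the WT MP and mCre TN libraries on the first principal component (24.8 and 11.04) and held 64.0% and 60.2% let-7. The Sfmbt2 median moved from -1.22 to -0.51 with the GC trend removed. In the miR-99/100/125 clusters, miR-99b-5p and miR-125b-5p passed adjusted over the list alone, and in the activation list miR-146a-5p and miR-21a-5p. The activation list as a whole did not pass in mCre, with 5 of 8 members higher (camera adjusted p = 0.2929, fry adjusted p = 0.1988). Its member miR-155-5p was 1195 ± 165 CPM in MP and 1026 ± 382.5 in TN. In the myeloid list miR-223-3p passed the same way, with 2 counts in MP and 49 in TN, while miR-223-5p went up. Left-out libraries moved the edgeR count to 56 (WT TN replicate 1), 41 (the library labelled WT TN replicate 2) and 2 (mCre TN replicate 1), and leaving out both TN replicate 2 libraries moved it to 30; without the filter on low counts it was 24. Across the 382 miRNAs the subset effects in WT and mCre had a Spearman correlation of 0.027, and 48.4% shared a sign; without both TN replicate 2 libraries the values were 0.542 and 71.1% (433 miRNAs). miRNAs are not independent replicates.

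The mCre genotype was compared with WT within TN, where the libraries labelled replicate 2 ran against their labels in miR-29. miR-150-5p, a miRNA of mature lymphocytes, was 120700 ± 46530 CPM in mCre and 47980 ± 2728 in WT, and miR-181a-1-3p 181.6 ± 46.2 and 67.6 ± 5.53 (SD, n = 2 each). miR-664-3p was 97.6 ± 34.6 and 27.8 ± 17.8 CPM, and miR-8120 0.845 ± 0.215 and 5.98 ± 4.29. miR-21a-3p, the minor strand of the miR-21 hairpin, had 61 counts in mCre and 1 in WT, a ratio of 37.1 with an exact 95% interval of 6.42 to 1490 from counting alone. These had the 5 smallest p and none passed: edgeR's quasi-likelihood test called 0 of 382 (smallest edgeR adjusted p = 0.9568) with 12 at an unadjusted p under 0.05, fewer than the 19.1 expected by chance, and DESeq2 called 0. The 3p forms of miR-29a, miR-29b and miR-29c changed by 2.24 ± 1.16, 2.33 ± 1.15 and 1.99 ± 1.44 on the log2 scale towards the libraries labelled mCre; without the library labelled mCre TN replicate 2 the values were -0.38, -0.47 and -0.11, and without both TN replicate 2 libraries -0.98, -0.96 and -1.02. The last exclusion was chosen from the same miR-29 levels, so it is no independent check of them. No list passed in camera. By fry the miR-183 cluster was lower in mCre (fry adjusted p = 0.04488, camera adjusted p = 0.07579). Its log2 changes were negative in 3 of 3 members, with 0 past the threshold adjusted over the list alone.

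The mCre genotype was compared with WT in MP, where the miR-29 family share was lower in both libraries labelled mCre. miR-29a-3p changed by -2.66 ± 1.18, miR-29b-3p by -2.41 ± 1.16 and miR-29c-3p by -2.50 ± 1.48 on the log2 scale (SE, edgeR adjusted p = 0.4109, 0.4109 and 0.4533). miR-29a-5p had 0 counts in mCre and 29 in WT, 6.97-fold lower with the floor of 3 counts taken over the group. The exact 95% interval of the mCre to WT ratio ran from 0 to 0.188, from counting alone. let-7a-5p was 168700 ± 35750 CPM in mCre and 58230 ± 11760 in WT, and let-7c-5p 41220 ± 13130 and 10900 ± 929.8 (SD, n = 2 each). miR-93-5p of the miR-17-92 paralogs was 143.3 ± 55.8 and 639.2 ± 32.9 CPM, and miR-23a-3p 500.7 ± 251.8 and 2117 ± 110.4. The 5 smallest p belonged to let-7i-3p, miR-1943-5p, miR-339-5p, miR-32-3p and miR-664-3p; miR-664-3p was 29.8 ± 10.7 CPM in mCre and 121.3 ± 1.51 in WT, and miR-1943-5p 78.8 ± 50.3 and 13.7 ± 0.108.

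edgeR's quasi-likelihood test called 0 of 382 miRNAs for mCre against WT in MP (smallest edgeR adjusted p = 0.4109), with 41 at an unadjusted p under 0.05, 14 higher and 27 lower, and DESeq2 called 0. The 4-group fit shares its estimate of the spread, so the TN pairs entered this MP comparison. Log2 differences between replicates had an SD over miRNAs of 1.863 in WT TN and 1.378 in mCre TN. In MP the SD was 0.755 in WT and 1.22 in mCre. The groups did not overlap for 247 miRNAs (64.7%, against 33.3% by chance). The let-7 list was higher in 7 of 9 members and the miR-17-92 list lower in 12 of 13 by camera (both adjusted p = 0.01492; both 0.6895 as adjusted p with an estimated correlation), with 0 members of either past the threshold over all miRNAs or adjusted over the list alone. These directions held under the 3 other scalings. In the myeloid list miR-223-3p, a miRNA of granulocytes and monocytes, had 2 counts in mCre and 48 in WT, a ratio of 0.0578 (exact 95% interval 0.0068 to 0.22), and passed adjusted over the list alone. The mCre MP libraries held 64.0% and 60.2% let-7 and 420 and 522 detected miRNAs, against 43.5% and 46.2% and 588 and 595 in WT MP. A fit of these 4 libraries alone called 23 miRNAs, and one without both TN replicate 2 libraries called 63, 20 higher and 43 lower.

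The difference of the genotype effect between MP and TN asks whether mCre acted differently in the subsets. Among the miR-29 forms, miR-29a-3p differed by -4.90 ± 1.66 and miR-29b-3p by -4.74 ± 1.63 on the log2 scale (SE, edgeR adjusted p = 0.3004 for both), and both passed adjusted over the list alone, together with miR-29a-5p. Of the 6 tested forms, 5 went down and 1 up. The TN side of these differences rests on the replicate 2 libraries as labelled; without them the miR-29 list median moved from -4.61 to -1.47. miR-150-5p (-2.02 ± 0.60), miR-342-3p (-3.24 ± 1.02) and miR-26b-5p (-3.69 ± 1.19) of the resting lymphocyte list also passed adjusted over the list alone and not over all miRNAs. Without both TN replicate 2 libraries the median of that list moved from -1.26 to -0.36. In the myeloid list miR-223-3p went down and passed adjusted over the list alone. miR-664-3p (-3.82 ± 0.89), let-7i-3p, miR-296-5p, miR-21a-3p and let-7c-5p (3.01 ± 0.86) had the 5 smallest p. edgeR's quasi-likelihood test called 0 of 382 (smallest edgeR adjusted p = 0.3004), with 54 at an unadjusted p under 0.05, and DESeq2 called 16. Without WT TN replicate 1 edgeR called 68, without the filter on low counts 10, and without both TN replicate 2 libraries 0. The let-7 list went up and the miR-17-92 list down in this difference (camera adjusted p = 0.03269 for both; 0.7271 as adjusted p with an estimated correlation). Their TN side rests on the same replicate 2 libraries: without them the let-7 median moved from 1.10 to 0.45 and the miR-17-92 median from -1.59 to -0.80 on the log2 scale.

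Over both subsets, no miRNA passed the threshold between mCre and WT. miR-29a-3p was 4784 ± 7080 CPM in the libraries labelled mCre and 4579 ± 4827 in those labelled WT (SD, n = 4 each), and miR-29b-3p 206.8 ± 305.0 and 181.2 ± 178.0. Without both TN replicate 2 libraries, an exclusion chosen from miR-29 itself, the miR-29 list median moved from -0.17 to -1.96 on the log2 scale and the change of miR-29a-3p from -0.21 to -2.10. The 5 smallest p were those of miR-92b-5p, miR-296-3p, miR-1187, miR-505-5p and miR-7658-5p; miR-296-3p was 98.8 ± 35.4 and 50.4 ± 19.7 CPM, and miR-505-5p, at 4.84 ± 1.08 and 1.84 ± 0.604, was the one of them with no overlap; in all, 5 of 382 miRNAs (1.3%) had none, against 2.9% by chance. edgeR's quasi-likelihood test called 0 of 382 (smallest edgeR adjusted p = 0.9923), with 5 at an unadjusted p under 0.05, and DESeq2 called 0. The miR-23/27/24 list was lower in 7 of 7 members (camera adjusted p = 0.03775; 0.7577 as adjusted p with an estimated correlation) and the miR-30 list in 5 of 5 (camera adjusted p = 0.04562; 0.7577 as adjusted p with an estimated correlation), with 0 members of either past the threshold over all miRNAs or adjusted over the list alone. Both mCre MP libraries, which were rich in let-7 (64.0% and 60.2%) and scored 24.8 and 11.04 on the first principal component, held 0.654% and 0.962% miR-23/27/24, and the library labelled WT TN replicate 2 0.895%, against 1.21% to 2.82% in the other 5. The miR-30 family held 1.38% to 1.73% in these 3 and the library labelled mCre TN replicate 2, and 2.99% to 4.06% in the other 4. Without both TN replicate 2 libraries the medians of these lists moved from -0.51 to -0.80 and from -0.75 to -1.29 on the log2 scale, and edgeR called 27 miRNAs, 10 higher and 17 lower. Across the 382 miRNAs the genotype effects in TN and MP had a Spearman correlation of -0.419, and 34.3% shared a sign; without both TN replicate 2 libraries the values were 0.405 and 65.4% (433 miRNAs), so the sign rests on those libraries as labelled.

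The largest component of variation followed neither label. The first principal component held 51.7% of the variance and placed the library labelled WT TN replicate 2 (15.3) with both mCre MP libraries (24.8 and 11.04), while the other 5 scored from -19.8 to -4.00. The second held 16.7% and ordered the subsets: MP libraries scored from 3.23 to 11.3 and TN libraries from -14.3 to 0.12. By Spearman correlation over miRNAs, the library labelled WT TN replicate 2 was closest to mCre MP replicate 2 (0.928), and the library labelled mCre TN replicate 2 to WT TN replicate 1 (0.923). mCre TN replicate 1 was also closest to WT TN replicate 1 (0.952), so nearness to that library does not tell the genotypes apart.

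**Figure D3:**
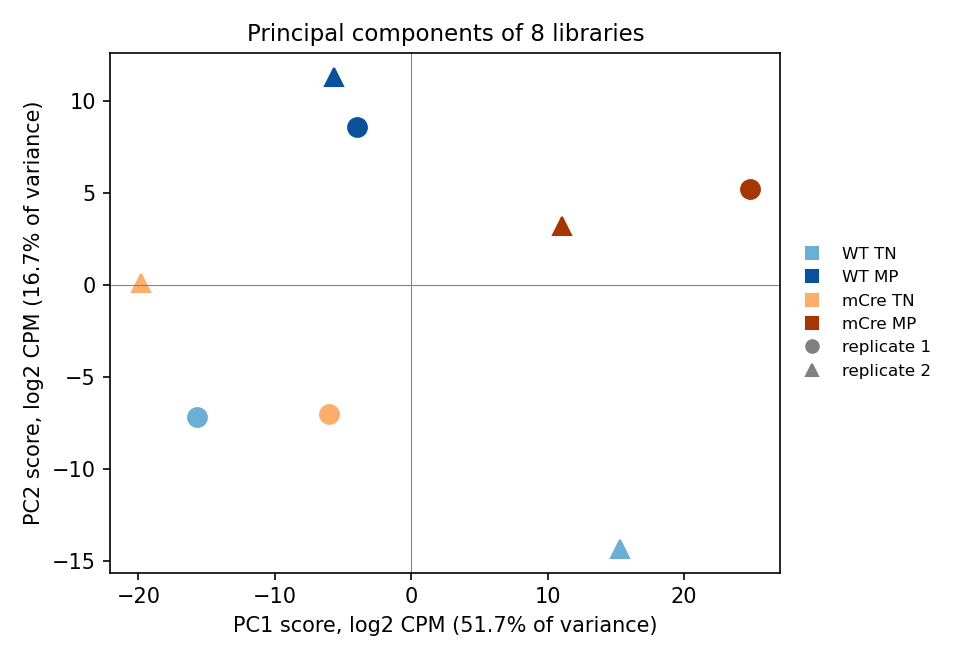
Scores of the 8 libraries on the first principal component (horizontal axis, 51.7% of the variance of log2 CPM) and the second (vertical axis, 16.7%); colours are groups as labelled, circles replicate 1 and triangles replicate 2. The library labelled WT TN replicate 2 sits at 15.3 on the first component, beside mCre MP, and the second separates MP (3.23 to 11.3) from TN (-14.3 to 0.12).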

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

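The fit without both TN replicate 2 libraries, the mean of rows and the GC-trend correction were chosen after seeing the data. The miR-29 group shares moved by less than 1 SD with the 3p forms alone or without the most abundant miRNA. The 9 miRNAs called for MP against TN over both genotypes kept their direction under all 17 alternatives; miR-181a-2-3p stayed past the threshold in 14 of them and miR-30c-2-3p in 5. Single miRNAs were followed in 102 results: the tested miR-29 forms, the called miRNAs, those with the smallest p and the list examples named in the results. Of these, 585 values under other scaling, filter, tool, block or 2-group fits stayed on their side of the threshold with their sign, 53 newly passed, 10 were lost and 10 changed sign; with a library left out these numbers were 685, 33, 57 and 41, and under the added alternatives 258, 32, 2 and 14. List calls were kept in 5 cases, all by fry, and lost in 31 with an estimated correlation or fry. At 1 to 3 counts a group, as for miR-21a-3p and let-7i-3p, depth limits the ratio. Where no cause is given below, the cause was not tested.

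No filter on low counts gave 1 call for mCre against WT in TN, 6 for MP against TN in WT, 24 in mCre, 10 for the difference of the genotype effect and 19 for MP against TN over both genotypes. DESeq2 gave 12, 44, 16 and 28 for the last 4 of these. The 2-group fit gave 23 calls for mCre against WT in MP. Without both TN replicate 2 libraries there were 63 for mCre against WT in MP, 14 for MP against TN in WT, 30 in mCre, 27 for mCre against WT over both subsets and 49 for MP against TN over both genotypes. Replicate numbers did not pair the samples (correlations of deviations from -0.32 to 0.407); with the replicate number as a block, MP against TN over both genotypes had 2 calls and the other comparisons 0. Leaving out 1 library at a time gave 0 to 6 calls for MP against TN in WT, 0 to 56 in mCre, 0 to 68 for the difference of the genotype effect and 0 to 41 for MP against TN over both genotypes; a group left with 1 library is assumed to vary like the others. The extremes came without WT TN replicate 1 (6, 56 and 68) and without the library labelled WT TN replicate 2 (41). For MP against TN over both genotypes, 1 call was left without WT TN replicate 1 or mCre TN replicate 1, 2 without the library labelled mCre TN replicate 2 or mCre MP replicate 1, and 0 without WT MP replicate 1, WT MP replicate 2 or mCre MP replicate 2. Scaling moved the median log2 fold change of all miRNAs by up to -0.31 (total counts, MP against TN in mCre) and 0.32 (TMM without miR-29, difference of the genotype effect).

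Reversals of sign among these 102 results were all in miR-29 forms, none past the threshold in the main test. miR-29b-1-5p, at about 4 to 6 CPM, had a log2 change of 0.01 for mCre against WT in TN and -0.11 (RLE), -0.009 (total counts), -0.15 (TMM without miR-29), -0.11 (DESeq2), -0.002 (replicate block), -0.16 (2-group fit), -0.055 (without both TN replicate 2 libraries), -0.16 (mean of rows) and -0.26 (GC trend). It also reversed to 0.041 (GC trend) for mCre against WT in MP, to -0.12 (total counts) and -0.055 (replicate block) for MP against TN in mCre, and to 0.059 (TMM without miR-29), 0.031 (mean of rows) and 0.30 (GC trend) for the difference of the genotype effect. Without both TN replicate 2 libraries, miR-29a-3p, miR-29b-3p and miR-29c-3p reversed to -0.98, -0.96 and -1.02 for mCre against WT in TN, and miR-29a-3p and miR-29b-3p to 0.36 and 0.58 for MP against TN over both genotypes. The GC trend gave 0.13 and 0.24 for the latter and 0.04 for miR-29b-3p in mCre against WT over both subsets; total counts gave -0.13 for miR-29c-3p in MP against TN over both genotypes.

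Leaving out 1 library at a time, the ranges for mCre against WT in TN were -0.38 to 3.40 for miR-29a-3p, -0.47 to 3.23 for miR-29b-3p, -0.11 to 9.35 for miR-29c-3p, -4.69 to 4.05 for miR-29c-5p and -0.15 to 0.11 for miR-29b-1-5p; the lowest values of the 3p forms came without the library labelled mCre TN replicate 2. miR-29b-1-5p ranged from -3.38 to 0.68 for mCre against WT in MP, -2.98 to 1.14 for MP against TN in mCre and -3.35 to 0.83 for the difference of the genotype effect, where miR-29c-5p ranged from -3.06 to 5.69. For mCre against WT over both subsets the ranges were -1.68 to 0.78 (miR-29a-3p), -2.37 to 0.38 (miR-29a-5p), -0.97 to 0.2 (miR-29b-1-5p), -1.58 to 0.89 (miR-29b-3p), -1.48 to 0.64 (miR-29c-3p) and -0.26 to 1.28 (miR-29c-5p). For MP against TN over both genotypes they were -1.58 to 0.90 (miR-29a-3p), -2.47 to 0.22 (miR-29a-5p), -0.56 to 0.66 (miR-29b-1-5p), -1.44 to 1.03 (miR-29b-3p) and -0.95 to 1.18 (miR-29c-3p).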

Other observations

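Of the tests in this part, those on exchanged labels, incomplete deletion, depth, genotype on the first component and the GC-trend removal were chosen after the result was seen. The libraries differed in how their counts were spread. The let-7 family held 69.5%, 64.0% and 60.2% of the counts in the library labelled WT TN replicate 2 and in mCre MP replicates 1 and 2, and 43.5% to 52.2% in the other 5. miR-150-5p held 4.22%, 3.84% and 6.09% in these 3 and 6.16% to 15.2% in the others. The miR-15/16 family held 1462, 1245 and 2354 CPM without TMM scaling in the 3 libraries and 6383 to 14200 in the others.

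miR-29 in the TN replicate 2 libraries ran against their genotype labels. A loss of low-GC miRNAs from the library labelled WT was tested by matching on GC. The median difference of the 3 miR-29 3p forms, 4.26 on the log2 scale, lay at percentile 99.9 of 10000 GC-matched random sets, whose median was 0.93. The 3 forms thus differed more than most miRNAs of like GC. They belong to 1 family and move together, unlike the random sets, so the percentile overstates how unusual they are and cannot settle this cause. Incomplete deletion behind the library labelled mCre, with all labels right, leaves the low WT library unexplained, since its miR-29 share was 0.218 of the lowest of the other 3 WT libraries. An exchange of these labels may account for both: without the miR-29 family, the mCre minus WT difference in MP correlated at -0.64 (Spearman, 376 miRNAs) with that in TN replicate 2 and at 0.443 with that in TN replicate 1. That evidence overlaps with the composition shift described next, so an exchange stays a hypothesis that the labels alone cannot settle, and another cause of low miR-29 in a WT sample, such as a difference between animals, was not tested.

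The 3 libraries rich in let-7 also detected fewer miRNAs. Lower total depth is argued against: after thinning every library to 1900000 counts, their highest number was 496 miRNAs, below the median of 549 in the other 5, of which 1, the library labelled mCre TN replicate 2, had 490. Thinning evens out the totals but not the counts left beside let-7. Fewer detected miRNAs may thus follow from the let-7 share, and the test cannot treat them as a separate trait. Genotype as labelled was set against the scores on the first component. The mCre TN libraries scored -6.00 and -19.8, below the highest score, -4.00, of the WT libraries outside the pattern. That highest score is of WT MP replicate 1, a library of the other subset. Within TN replicate 1, mCre (-6.00) lay above WT (-15.7), the direction seen in MP. The case against genotype as the whole cause thus rests on the TN replicate 2 libraries as labelled, at 15.3 in WT and -19.8 in mCre. It does not hold for exchanged labels, and a genotype effect in MP alone stays open. A loss of low-GC miRNAs remains a candidate explanation for part of the shift, because the loadings of that component correlated with the GC content of the hairpin arm at 0.29 (Spearman). Removing the GC trend per library left 8 calls for MP against TN over both genotypes, 8 of the 9, so the trend as modelled is not the whole of that subset difference. For mCre against WT in MP, the removal widened the let-7 list median from 0.764 to 1.088. It narrowed the miR-17-92 median from -1.964 to -1.65 and the miR-15/16 median from -1.987 to -1.72. The trend as modelled thus left these 3 list differences largely in place.

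Other splits of the 8 libraries into 4 and 4, of which 34 could be fitted beside the other factor, were counted by their number of calls. For MP against TN over both genotypes, 1 of 34 splits, the real one, gave 9 calls, and the highest other gave 6; only 18 of them are balanced within genotype as the real one is, which is too few for a share under 0.05, and the highest other of these gave 0. For mCre against WT over both subsets the real count was 0, which 34 of 34 splits reach by construction, so they say nothing about chance there. The highest other split gave 31 calls, which points to a structure of the samples apart from the labels. That split set WT TN replicate 1, both WT MP libraries and the library labelled mCre TN replicate 2 against the other 4; it is the one an exchange of the TN replicate 2 labels would give, and, apart from mCre TN replicate 1 (-6.00), it also follows the scores on the first component.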
